A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

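The series measured RNA of 5 strains on 9 Agilent yeast arrays with 2 channels, 1 array per sample. Groups were taken from the labels, with 3 arrays of BY4716, 3 of RM11-1a and 1 each of YAD350, YLK804 and YLK806. RNA was extracted with hot acid phenol and cleaned on columns, per the labels' protocols.

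The deposited scanner files hold the intensity of each spot in each channel, with its local background, and the images were read with Agilent Feature Extraction 8.5.1.1 for 7 arrays and 9.1.3.1 for YLK804 and YLK806, per the file headers. The same files hold a deposited log10 ratio of Cy5 over Cy3, made by that software after background subtraction with spatial detrending and a rank-consistent lowess dye normalization, per the file headers. The series value table holds log2 ratios deposited by the authors. They equalled the scanner's ratios on the log2 scale within 0.0005 on every array, so scale and direction are known, and each column's median lay between 0 and 0.008, with no further centring seen. No column of another sample was found in that table.

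From the intensities, mean signals were corrected with normexp with an offset of 50 in limma 3.58.1 under R 4.3.3, and normalized by loess within each array. Control spots had weight 0 in the loess and were left out afterwards, as were spots with an outlier flag, between 5 and 140 per array. Saturated spots were kept. Of 10789 spots per array 10263 were gene spots for 6256 genes, and spots of a gene were averaged. Each gene had 1 probe, and 4007 genes had 2 spots. Gene names came from the R64 annotation, which matched 5756 systematic names, and the files' names were kept otherwise. A gene entered when it was well above background in either channel on at least 3 of 9 arrays, which left 5865 genes. The offset draws log2 ratios toward 0. On simulated intensities with 200 changed genes, run on 5865 genes, the median estimate for the parental comparison was 0.816 of the true log2 difference at 1.5-fold, 0.801 at 2-fold and 0.791 at 4-fold.

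Depth on an array is signal over background. Median strain signals lay between 237 and 424 and median reference signals between 179 and 272, over median backgrounds between 21 and 32. Between 89.5% and 93.9% of genes were well above background in the strain channel. Where a gene was well above background on no array of a group, a fold is given as "at least", the mean of the brighter group over the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. These values are per channel after loess and Aquantile and are open to dye bias, since no dyes were swapped.

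One model with 5 groups was fitted to all 9 arrays with limma's lmFit and eBayes, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The spread comes from the 6 parental arrays, with 4 residual degrees of freedom, and a strain with 1 array was assumed to vary like them. Comparisons were RM11-1a with BY4716, YAD350 and YLK804 with BY4716, YLK806 with RM11-1a, and the SAL1 alleles averaged over both backgrounds. Before the data were examined, 38 gene lists were fixed, and the 36 not described gene by gene were tested with camera at a correlation of 0.01 and again with an estimated one. Errors written as SE come from the fit.

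The labels of the 3 exchange strain arrays disagree on the dye. The rule, fixed before the data were examined, was to read the strain as Cy5 unless the array's r with its background parent was under -0.3. Named genes were, for the parents, the 8 largest rises and 8 largest falls, and 5 of each elsewhere, among called genes whose arrays did not overlap between groups. In the SAL1 contrast the 2 backgrounds also had to differ in sign. The 3 members with the smallest p were added for each list that passed, and the marker, mating type and exchanged-interval genes were always allowed. BAT1, URA4, COS8, GSC2, SNZ2, YIR043C, the genes of the mitochondrial genome and the neighbours of the deleted markers were chosen after their values were seen.

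In the self-test, 100% of genes changed by 2-fold were recovered for the parental comparison, run on 5865 genes. For YAD350, also on 5865 genes, 85.1% were recovered at 1.5-fold and 94.0% at 2-fold. The simulated arrays held no difference of scan day or reference, so these shares do not cover such a shift in the exchange strains. Alternatives covered background correction, normalization, filters, the deposited ratios, the intensity trend, scan day, replicate number and each parental array left out. Of 6 scan days 1 held arrays of both parental strains and another held YLK804 and YLK806.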

Results

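Transcript levels were measured in 5 strains of the budding yeast Saccharomyces cerevisiae on 9 arrays with 2 colours. BY4716, a laboratory strain, and RM11-1a, a strain derived from a vineyard isolate, had 3 arrays each. The other 3 strains carried an exchanged allele and had 1 array each. YAD350 had a single amino acid replacement in MKT1 in the laboratory background BY4742, YLK804 had the RM11-1a allele of SAL1 in the laboratory background BY4724, and YLK806 had the BY allele of SAL1 in RM11-1a. MKT1 encodes a protein that acts on messenger RNAs after transcription, and SAL1 encodes a mitochondrial carrier of adenine nucleotides. The cells grew in minimal medium with 2% glucose, and YAD350 also received histidine at 20 mg/L. Each strain was labelled with Cy5 and set against a common reference labelled with Cy3, a pool of RNA from both parental strains grown on glucose and on ethanol. Between 5601 and 5872 of the 6256 genes on an array were well above background in the strain channel, and the number of arrays limits the precision. Nothing in the labels says that the 3 arrays of a parental strain came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

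The marker genes were examined first, because they check the labels. URA3, which encodes an enzyme of uracil synthesis, was at a log2 ratio of 1.38 ± 0.03 (SD, n = 3) in BY4716 and at -2.49 ± 0.12 (SD, n = 3) in RM11-1a, where 1 of 3 arrays measured it well above background. It was at -2.89 in YAD350, -3.47 in YLK804 and -3.04 in YLK806. LEU2, for leucine synthesis, was not well above background in RM11-1a, YAD350 and YLK806, and it was at least 19.5-fold higher in BY4716 than in RM11-1a. LYS2, for lysine synthesis, was at -3.15 ± 0.14 (SD, n = 3) in BY4716, -3.16 in YAD350 and -3.84 in YLK804, against 0.96 ± 0.04 (SD, n = 3) in RM11-1a and 1.00 in YLK806. HIS3, for histidine synthesis, was low in YAD350 alone, at -4.20, and lay between 0.15 and 0.30 on the other 8 arrays. HO, the mating type switching endonuclease, was at 1.18 ± 0.07 (SD, n = 3) in BY4716 and -2.84 ± 0.16 (SD, n = 3) in RM11-1a, where 2 of 3 arrays measured it. STE2, the receptor of MATa cells, was high in RM11-1a, YLK804 and YLK806, and STE3, the receptor of MATalpha cells, was high in BY4716 and YAD350. MKT1 and SAL1 check nothing by level, since the exchanges need not alter the amount of transcript. MKT1 was at 0.03 ± 0.04 (SD, n = 3) in BY4716, -0.40 ± 0.09 (SD, n = 3) in RM11-1a, 0.05 in YAD350, 0.20 in YLK804 and -0.12 in YLK806, and SAL1 was at -0.65 in YLK804 and between -0.17 and -0.03 on the other 8 arrays.

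**Figure D1:**
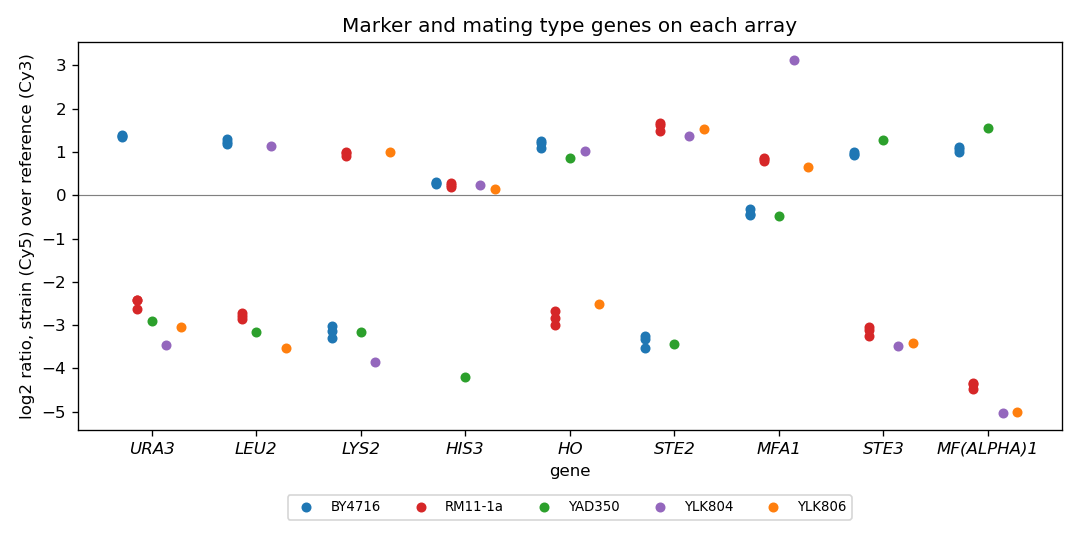
Log2 ratio of strain over reference (vertical axis) for 5 marker genes and 4 mating type genes (horizontal axis), with 1 point per array coloured by strain. HIS3 was low on the YAD350 array alone, at -4.20, and MFA1 was highest on the YLK804 array, at 3.12.

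The labels of the 3 arrays of the exchange strains disagree on which dye held the strain. Each array correlated with its background parent across genes, with r = 0.806 for YAD350, 0.878 for YLK804 and 0.886 for YLK806, so the strain was read as Cy5 on all 9 arrays. Genes are not independent replicates, and no p is given for these correlations.

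The comparison of RM11-1a with BY4716 asked how the 2 parental backgrounds differed. In RM11-1a, 38 of 39 measured subunits of oxidative phosphorylation rose and 1 fell, with a median log2 difference of 1.21, including NDE1 at 1.86 ± 0.06, ATP5 at 1.40 ± 0.04 and COX7 at 1.29 ± 0.05 (SE). Mitochondrial ribosomal protein genes rose in 67 of 70 cases and none fell, with a median of 0.47, among them MRPL39 at 1.62 ± 0.06, MRP20 at 0.73 ± 0.05 and MRPL23 at 0.65 ± 0.05 (SE). Of 36 environmental stress genes 32 rose and 3 fell, with a median of 1.25. Among them were TMA10 at 2.60 ± 0.11, RTN2 at 2.41 ± 0.10 and DDR2 at 1.99 ± 0.09 (SE). Genes of daughter cell separation fell in 11 of 12 cases, with DSE1 at -3.09 ± 0.07, DSE2 at -2.81 ± 0.09 and the glucanase gene SCW11 at -2.15 ± 0.06 (SE). With an estimated correlation the adjusted p was 0.515 for oxidative phosphorylation, 0.621 for the mitochondrial ribosome and the stress genes, and 0.361 for cell separation.

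Further groups changed between the parents. Of 20 genes that depend on heme or on the heme-responsive factor Hap1, 18 rose and 1 fell, among them the flavohemoglobin gene YHB1 at 2.70 ± 0.08 and the sterol synthesis gene HMG1 at 1.43 ± 0.05 (SE). Ergosterol genes rose in 19 of 24 cases, with ERG28 at 1.27 ± 0.05 and ERG9 at 0.92 ± 0.03 (SE), and none fell. Phosphate starvation genes fell in 14 of 16 cases and 1 rose. The phosphate transporter genes PHO84 and PHO89 were at -5.01 ± 0.09 and -1.67 ± 0.05 (SE), and SPL2, not well above background in RM11-1a, was at least 11.3-fold higher in BY4716. Ribosome biogenesis genes fell in 35 of 48 cases, including NOP4 at -0.78 ± 0.04, RPA34 at -0.67 ± 0.05 and RPA43 at -0.60 ± 0.04 (SE), and none rose. The 2 strains differ in mating type, so the results of both mating type lists were fixed in advance and check the labels. All 7 MATa genes rose, with STE6 at 3.81 ± 0.04 and MFA2 at 3.20 ± 0.05 (SE). All 4 MATalpha genes fell, with MF(ALPHA)1 at -5.45 ± 0.05 and SAG1 at -3.39 ± 0.08 (SE). In the pheromone response 12 of 21 genes fell and 4 rose, with PRM5 at -2.17 ± 0.05 and FUS1 at -0.82 ± 0.04 (SE), and PRM8, not well above background in RM11-1a, at least 1.96-fold higher in BY4716. With an estimated correlation the adjusted p of the ribosome biogenesis list was 0.449, and that of the other 6 lists was 0.361.

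Changes were also found in 6 more groups. Mitochondrial translation factors rose in 31 of 46 cases and fell in 2, with MEF2 at 1.01 ± 0.08, COX18 at 0.47 ± 0.05 and MSR1 at 0.29 ± 0.03 (SE). Genes of the tricarboxylic acid cycle rose in 13 of 17 cases, with MDH1 at 1.05 ± 0.10, LSC1 at 0.78 ± 0.07 and LSC2 at 0.76 ± 0.08 (SE). Of 22 mitochondrial carrier genes 15 rose and 2 fell, with OAC1 at 1.82 ± 0.05, DIC1 at 1.77 ± 0.06 and the phosphate carrier gene MIR1 at 1.32 ± 0.08 (SE). Sulfur and methionine genes fell in 11 of 21 cases and 2 rose, with the sulfate permease gene SUL1 at -1.41 ± 0.04, MET32 at -0.51 ± 0.04 and SAM2 at 0.88 ± 0.04 (SE). Proteasome genes rose in 15 of 31 cases and fell in 3, with PRE7 at 0.72 ± 0.05, PRE4 at 0.42 ± 0.03 and RPN9 at 0.33 ± 0.04 (SE). Of 23 genes at loci of variable copy number 13 fell and 6 rose, and the asparaginase copies ASP3-1 to ASP3-4, near-identical genes whose probes can share signal, lay between -5.54 and -5.46. For these 6 lists the adjusted p lay between 0.449 and 0.764 with an estimated correlation.

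Single genes with the largest rises were STE2 at 4.95 ± 0.08, INO1, for inositol synthesis, at 4.80 ± 0.09, PHM7 at 4.19 ± 0.10, LYS2 at 4.12 ± 0.07 and STE6 (SE). The high-affinity hexose transporter genes HXT7 and HXT6 rose by 3.52 ± 0.18 and 3.49 ± 0.16, and the catalase gene CTT1 rose by 3.48 ± 0.30 (SE). Large falls were seen in the ASP3 copies, PHO84 and MF(ALPHA)1, the last well above background on 2 of 3 RM11-1a arrays, and STE3, well above background on 1 of 3 RM11-1a arrays, was at -4.09 ± 0.06 (SE). Of these, STE2, STE6, STE3 and MF(ALPHA)1 follow mating type and LYS2 is a marker gene, so they check the labels. In the deposited Agilent ratios, to which no offset was added here, PHO89 was at -3.67 and STE3 at -6.92. Every gene given here as rising or falling had a limma adjusted p under the threshold, and the adjusted p was 8.7e-09 for ASP3-1 and 4e-05 for CTT1.

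In total 3697 of 5865 genes passed the test, 1940 higher and 1757 lower in RM11-1a, and 335 of them differed by at least 2-fold. Each gene had 1 probe, and mismatches between RM11-1a and the probes were not checked. A difference between the parents can therefore also reflect sequence rather than the amount of transcript. The arrays of the 2 strains did not overlap for 4122 of the 5865 genes, or 70.3%, where chance gives 1 in 10. By camera with a preset correlation of 0.01, 17 of 36 lists passed. None of the 17 passed with an estimated correlation. The 2 mating type lists, fixed in advance by mating type, also failed, with an adjusted p of 0.361 by camera. Failing that test alone therefore does not show that a list was unchanged. The estimated correlation was 0.73 for the mitochondrial ribosome and 0.68 for oxidative phosphorylation, so the preset 0.01 is lenient for them. In the Agilent ratios the sulfur and methionine, variable locus and proteasome lists did not pass. The variable loci also failed without BY4716 replicate 9, and the proteasome without RM11-1a replicate 7 or 11. No median of a passing list changed sign under the other scalings tried, in this or the other comparisons, but 14 of 147 moved by over 1.5 times. Among the parental ones, the variable loci moved from -0.21 to -0.69, the pheromone response from -0.24 to -0.50 and the MATalpha genes from -3.74 to -6.52 in the Agilent ratios, and the variable loci to -0.11 with median centring. Adjusted over the list alone, the member counts were the same in 14 of these 17 lists. The mitochondrial ribosome then had 68 that rose, the proteasome 14 and the variable loci 7. The lists that did not pass included cytosolic ribosomal proteins, with 35 of 132 that rose and 20 that fell, glycolysis, with 1 and 7 of 18, and iron uptake, with 9 and 2 of 19. One scan day held an array of each parental strain. On that day 3683 of 3694 called genes had the same sign and the medians of all 17 passing lists kept theirs. These arrays had helped to make the calls, and 3668 of the 3697 called genes did not overlap between the strains. The signs were thus nearly fixed in advance and do not test an effect of scan day. With the day as a block 3316 genes were called, but that difference rests on this 1 array of each strain, with 1 residual degree of freedom.

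**Figure D2:**
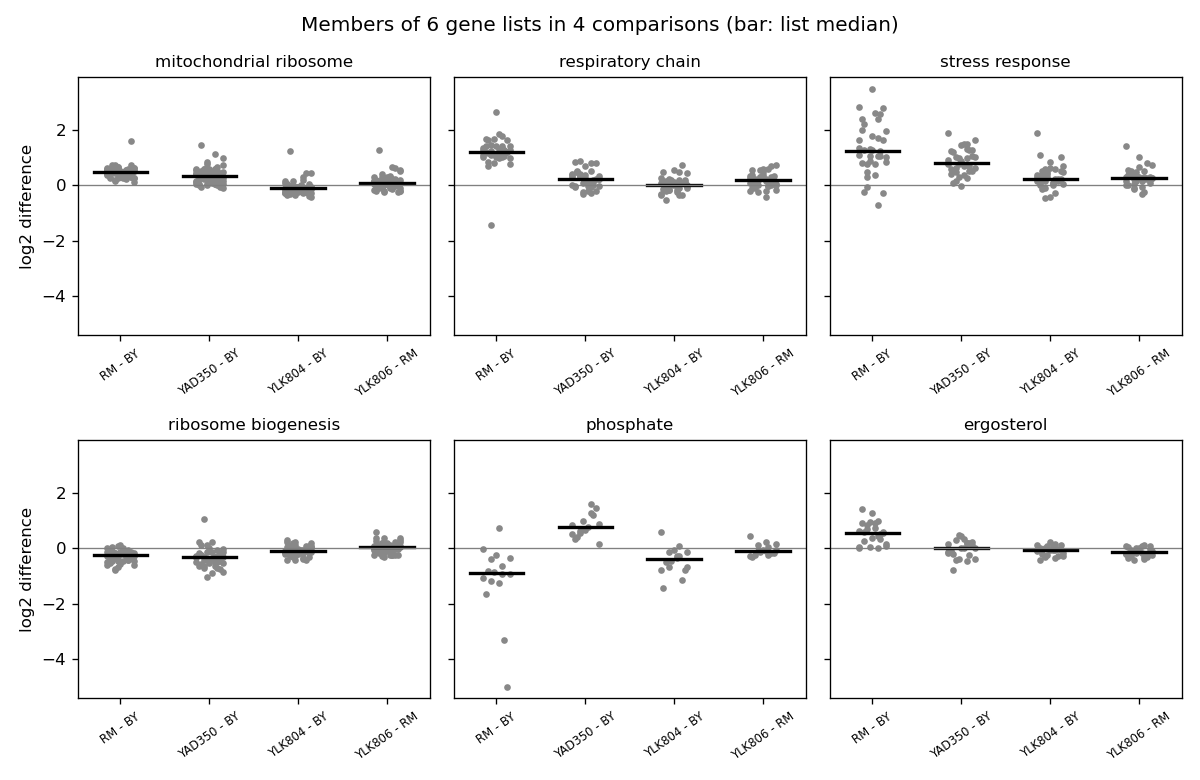
Log2 difference (vertical axis) of each measured member of 6 gene lists, 1 point per gene, in the comparisons named on the horizontal axis, with a bar at the list median. The median of the mitochondrial ribosome list was 0.47 in RM11-1a, 0.34 in YAD350, -0.12 in YLK804 and 0.09 in YLK806, and the phosphate list lay at -0.90 in RM11-1a and at 0.76 in YAD350.

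The comparison of YAD350 with BY4716 asked what the exchanged MKT1 allele altered. Mitochondrial ribosomal protein genes rose in 42 of 70 cases and none fell, with a median of 0.34, among them MRP4 at 1.12 ± 0.09, MRPL36 at 0.99 ± 0.10 and MRPL23 at 0.53 ± 0.06 (SE). Mitochondrial translation factors rose in 30 of 46 cases and fell in 1, with MSK1 at 0.70 ± 0.09, PET112 at 0.64 ± 0.08 and COX18 at 0.54 ± 0.07 (SE). Stress genes rose in 29 of 36 cases and none fell, with TMA10 at 1.49 ± 0.16, the trehalose synthesis gene TPS1 at 1.26 ± 0.10 and HSP78 at 0.69 ± 0.06 (SE). Ribosome biogenesis genes fell in 34 of 48 cases and 2 rose, with SSF1 at -1.06 ± 0.05, NOP8 at -0.89 ± 0.06 and NOP7 at -0.86 ± 0.07 (SE). Phosphate genes rose in 14 of 16 cases, with the acid phosphatase gene PHO5 at 1.61 ± 0.07, PHM6 at 1.26 ± 0.10 and VTC1 at 0.97 ± 0.06 (SE). For these 5 lists the adjusted p lay between 0.950 and 0.953 with an estimated correlation. Adjusted over the list alone, 45 mitochondrial ribosome genes, 31 translation factors, 30 stress genes and 3 ribosome biogenesis genes rose, 2 translation factors fell, and the phosphate count was the same. In a test chosen after the data were seen, the mean shift of YLK804 and YLK806 was subtracted. Then 37 mitochondrial ribosome genes, 13 translation factors, 19 stress genes and 13 phosphate genes rose, 26 ribosome biogenesis genes fell, and the median of the stress genes was 0.50 in place of 0.79.

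The other lists that passed were smaller or less uniform. Proteasome genes had lower ratios in 17 of 31 cases and higher ones in 2, with RPN10 at -0.60 ± 0.06, PRE10 at -0.60 ± 0.05 and RPT6 at -0.58 ± 0.06 (SE). Their median change was -0.062 in the Cy5 channel and 0.047 in the Cy3 channel, and with the mean shift subtracted 6 fell. Respiratory chain genes rose in 16 of 39 cases and fell in 2, with ATP18 at 0.82 ± 0.12, ATP19 at 0.68 ± 0.08 and ATP7 at 0.53 ± 0.08 (SE). Anaerobic and seripauperin genes rose in 13 of 17 cases, with PAU1 at 0.53 ± 0.08 and PAU6 at 0.47 ± 0.07, and AAC3 fell by 0.63 ± 0.07 (SE). Histidine genes fell in 4 of 7 cases, among them HIS5 at -0.35 ± 0.06 and HIS1 at -0.34 ± 0.07 (SE). The 4 include the deleted marker HIS3, whose fall was fixed in advance, and the list mean was -0.90 against a median of -0.25. YAD350 alone received histidine, which cannot be told apart from the MKT1 allele here. All 4 MATalpha genes rose, with MF(ALPHA)2 at 2.02 ± 0.10, MF(ALPHA)1 at 0.51 ± 0.07 and SAG1 at 0.47 ± 0.11 (SE). With an estimated correlation the adjusted p of these 5 lists lay between 0.950 and 0.953, so none of the 10 lists passed. Adjusted over the list alone, the counts of these 5 were the same. The respiratory chain list also failed without BY4716 or RM11-1a replicate 11 and with the mean shift of YLK804 and YLK806 subtracted, and its median moved from 0.23 to 0.099 with scaling between arrays. The MATalpha list failed in the Agilent ratios.

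The deleted markers HIS3, LEU2 and URA3 fell in YAD350, with differences of -4.48 ± 0.05 for HIS3 and -4.27 ± 0.08 for URA3 (SE), and LEU2 was at least 21.4-fold lower. PXR1 at -1.53 ± 0.22 and the peptide transporter gene PTR2 at -1.45 ± 0.27 followed, and URA1 at 2.19 ± 0.07, LEU1 at 2.17 ± 0.31, PSA1 at 2.06 ± 0.18 and MF(ALPHA)2 rose (SE). The ratio of YJL188C was higher by 3.06 ± 0.23 (SE), but its Cy5 channel changed by -1.12 and its Cy3 channel by -4.17. Beside the exchanged MKT1, the neighbouring genes SWS2 and END3 rose by 0.58 ± 0.09 and 0.28 ± 0.10 (SE), and PMS1 fell by 0.37 ± 0.09 (SE). PMS1 was also at -0.31 ± 0.09 in YLK804 and at -0.28 ± 0.09 in YLK806 (SE), so its fall was not particular to YAD350. SNN1 at 0.12 ± 0.05 and TCB2 at -0.22 ± 0.11 (SE) did not pass. Whether the exchange itself moved these neighbours was not tested. Rises and falls in YAD350 are of the ratio. The Cy3 channel changed more than the Cy5 channel for 12 of 44 called genes followed by name, among them TPS1, MRPL36, PXR1, PRE10, RPN10, PAU1, ATP18, ATP19 and END3. In total 2751 of 5850 genes passed, 1553 higher and 1198 lower, and 100 of them by at least 2-fold. YAD350 had 1 array, no replicate of its own and a scan day of its own, so it was assumed to vary like the parental arrays, and strain and batch cannot be told apart. In a comparison chosen after the data were seen, 1805 genes passed after the mean shift of the YLK804 and YLK806 arrays was subtracted.

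The comparison of YLK804 with BY4716 asked what the RM11-1a allele of SAL1 altered in a laboratory background, but the 2 strains also differed in mating type and URA3. All 7 MATa genes rose, with STE2 at 4.73 ± 0.11, STE6 at 4.10 ± 0.06, the protease gene BAR1 at 4.02 ± 0.09, the pheromone gene MFA1, well above background on 2 of 3 BY4716 arrays, at 3.53 ± 0.06 and MFA2 at 3.20 ± 0.08 (SE). All 4 MATalpha genes fell, with MF(ALPHA)1 at -6.08 ± 0.07, STE3 at -4.45 ± 0.08 and SAG1 at -3.50 ± 0.11 (SE), and MF(ALPHA)2 was not well above background and at least 7.7-fold lower. URA3 fell by 4.84 ± 0.08 (SE). SAL1 itself had a ratio lower by 0.51 ± 0.05 (SE), with a limma adjusted p of 0.0020, and changed by -0.25 in the Cy5 channel and 0.26 in the Cy3 channel.

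Phosphate genes fell in 9 of 16 cases in YLK804, with PHO89 at -1.44 ± 0.07, SPL2 at -1.14 ± 0.11 and PHO81 at -0.49 ± 0.06 (SE). Stress genes rose in 7 of 36 cases and fell in 1, with HSP12 at 1.87 ± 0.37, DDR2 at 1.11 ± 0.13 and GAD1 at 0.86 ± 0.18 (SE). Thiamine genes had lower ratios in 4 of 14 cases, with THI5 at -0.48 ± 0.05, THI12 at -0.36 ± 0.06 and THI11 at -0.29 ± 0.05 (SE), near-identical copies whose probes can share signal. Their Cy5 channel changed by -0.01, -0.01 and -0.04 and their Cy3 channel by 0.47, 0.35 and 0.25, and THI11 was well above background on 1 of 3 BY4716 arrays. Ribosome biogenesis genes fell in 10 of 48 cases and 1 rose, with BRX1 at -0.42 ± 0.06, SSF1 at -0.41 ± 0.05 and RPA49 at -0.35 ± 0.05 (SE). The mitochondrial ribosome list passed downward with a median of -0.12, although 3 members rose and 4 fell of 70, and the median change was 0.024 in the Cy5 channel and 0.12 in the Cy3 channel. Its members with the smallest p were MRP51 at 0.43 ± 0.08, MRPL8 at 1.24 ± 0.24 and MRPL6 at -0.42 ± 0.09 (SE). With an estimated correlation the adjusted p was 0.707 for phosphate, 0.331 for thiamine, 0.280 for both mating type lists and 0.999 for the other 3. Adjusted over the list alone, 12 stress genes and 1 phosphate gene rose, 6 thiamine genes fell, 1 mitochondrial ribosome gene fell, and the other counts were the same. Over the genes called in YLK804 outside the mating type, marker and pyrimidine genes, the Cy3 reference channel carried a share of 0.781 of the difference. Rises and falls here are of the ratio, and the Cy5 channel changed in the opposite direction for MRPL6, GAD1, RPA49 and DDR2, 4 of 31 called genes followed by name. The Cy3 channel changed more than the Cy5 channel for 12 of the 31, among them also PHO81, BRX1 and MRP51.

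In total 1238 of 5865 genes passed in YLK804, 642 higher and 596 lower, and 45 by at least 2-fold. Ribosome biogenesis did not pass without BY4716 replicate 11, nor the mitochondrial ribosome without replicate 9. With median centring 629 genes passed, and without BY4716 replicate 7 or 11 there were 592 and 625.

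The comparison of YLK806 with RM11-1a asked what the BY allele of SAL1 altered in the vineyard background. The metallothionein copies CUP1-1 and CUP1-2, for copper binding, were at 4.02 ± 0.47 and 4.06 ± 0.48 (SE), and they share nearly identical sequence. The mitochondrially encoded ATP8 and COB had higher ratios by 2.27 ± 0.10 and 1.62 ± 0.17 (SE), but ATP8 was not well above background in the strain channel of YLK806. The Cy5 channel changed by -0.16 for ATP8 and 0.12 for COB, and the Cy3 channel by -2.43 and -1.50. The ratio of YJL188C was higher by 1.80 ± 0.23 (SE), while its Cy5 channel changed by -2.68. TIS11, which acts in iron limitation, was at -2.77 ± 0.78, the copper chaperone gene ATX1 at -1.15 ± 0.13 and MFA2 at -0.81 ± 0.08 (SE). CRC1 and OST5 had ratio differences of -0.97 ± 0.14 and -0.82 ± 0.07 (SE), but their Cy5 channel was higher by 0.16 and 0.12. SAL1 was at 0.04 ± 0.05 (SE, adjusted p = 0.60 by limma).

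Mitochondrial translation factors rose in 11 of 46 cases in YLK806 and none fell, with PET111 at 0.46 ± 0.08, CBP1 at 0.45 ± 0.07 and PET494 at 0.36 ± 0.06 (SE). With median centring PET494 was at 0.19. Mitochondrial ribosome genes rose in 7 of 70 cases, with MRP4 at 0.66 ± 0.09, MRP51 at 0.62 ± 0.08 and MRPL36 at 0.54 ± 0.10 (SE). Respiratory chain genes rose in 7 of 39 cases and fell in 2, with ATP2 at 0.71 ± 0.12, ATP1 at 0.55 ± 0.12 and COX7 at -0.42 ± 0.07 (SE). Stress genes rose in 5 of 36 cases, with HSP12 at 1.43 ± 0.37, RTN2 at 0.54 ± 0.14 and TPS2 at 0.49 ± 0.14 (SE). Ergosterol genes fell in 5 of 24 cases, with ERG20 at -0.42 ± 0.08, ERG2 at -0.39 ± 0.06 and HMG1 at -0.34 ± 0.07 (SE), and thiamine genes fell in 6 of 14, with THI20 at -0.34 ± 0.06, THI5 at -0.33 ± 0.05 and THI4 at -0.28 ± 0.05 (SE). Proteasome genes fell in 7 of 31 cases and 1 rose, with SCL1 at -0.39 ± 0.06, PUP3 at -0.32 ± 0.05 and RPN5 at 0.81 ± 0.13 (SE). In iron uptake 2 of 19 genes fell, TIS11 and ATX1, and at variable loci 8 of 23 fell and 3 rose, where the list tested downward although its mean was 0.09, with SEO1 at -0.73 ± 0.11 (SE). Over all genes tested in YLK806, 632 of 5863 were higher and 683 lower. The counts for the mitochondrial ribosome, the stress genes and iron uptake lay near these shares. With an estimated correlation the adjusted p was 0.633 for thiamine and 0.963 for the other 8 lists. The Cy3 reference channel carried a share of 0.749 of the difference over the genes called in YLK806 outside the mating type, marker and pyrimidine genes. Rises and falls here are of the ratio. The Cy5 channel changed in the opposite direction for 13 of 39 called genes followed by name, ATP8, YJL188C, CRC1, OST5, MRPL36, CBP1, PET494, ATP2, PUP3, ERG20, HMG1, THI5 and THI20. The Cy3 channel changed more than the Cy5 channel for 22 of the 39, among them also HSP12, SEO1 and THI4. The median Cy5 change of the list was 0.11 for the proteasome and 0.07 for thiamine, opposite to the ratio.

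Adjusted over the list alone, 12 mitochondrial translation factors, 6 mitochondrial ribosome genes and 2 proteasome genes rose in YLK806, 8 thiamine genes, 10 genes at variable loci and 1 iron gene fell, none of the stress genes passed, and the ergosterol and respiratory chain counts were the same. In the deposited Agilent ratios 4 of the 9 lists passed, without ergosterol, the mitochondrial ribosome, the respiratory chain, the variable loci and the proteasome. The proteasome also failed without BY4716 or RM11-1a replicate 7 or 11, the respiratory chain without BY4716 replicate 11 or RM11-1a replicate 7, the mitochondrial ribosome without RM11-1a replicate 7 and ergosterol without RM11-1a replicate 9. In total 1315 of 5863 genes passed in YLK806, 632 higher and 683 lower, and 20 by at least 2-fold. With median centring 800 genes passed, and without BY4716 replicate 7 or 11 there were 865 and 856.

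The same share of the Cy3 channel was 0.355 in YAD350 and -0.037 between the parental strains. Of 18 genes of the mitochondrial genome, a group chosen after the values were seen, 15 had higher ratios in YAD350, 12 in YLK804 and 14 in YLK806, while in the mean of the 3 arrays their median change was -0.65 in the Cy3 channel and -0.14 in the Cy5 channel.

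The contrast of the SAL1 alleles averaged both backgrounds, with YLK804 minus BY4716 set against YLK806 minus RM11-1a. All 7 MATa genes rose and all 4 MATalpha genes fell, with STE2 at 2.40 ± 0.08, BAR1 at 2.08 ± 0.06, STE6 at 2.03 ± 0.04, MFA2 at 2.01 ± 0.05, MFA1 at 1.85 ± 0.04, MF(ALPHA)1 at -2.73 ± 0.05, STE3 at -2.08 ± 0.06 and SAG1 at -1.71 ± 0.08 (SE). MF(ALPHA)2 also passed, but RM11-1a, YLK804 and YLK806 had no array with it well above background, so no value is given. URA1 rose by 1.26 ± 0.05 and AFB1 fell by 1.17 ± 0.05 (SE). SUL1 at -0.32 ± 0.04 and YPL088W at -0.22 ± 0.03 (SE) were called with opposite signs in the 2 backgrounds, and YPL088W was at -0.097 in the deposited Agilent ratios. SAL1 was at -0.27 ± 0.04 (SE), and its change in YLK806 did not pass. In total 49 of 5863 genes passed, 27 higher and 22 lower, and 26 of them lay outside the listed mating type, marker and pyrimidine genes. The 26 still held AFB1, known as a gene of MATalpha cells, and, chosen after the values were seen, TIM9 beside URA3 and YCL021W-A beside LEU2. LEU2 was well above background in BY4716 and YLK804 and in neither RM11-1a nor YLK806, so its presence did not differ within either background. With the scan day as a block 156 passed, and without BY4716 replicate 7 or 9 there were 29 and 28.

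Both mating type lists passed in this contrast, with an adjusted p of 0.0759 with an estimated correlation. Phosphate genes fell in 2 of 16 cases, PHO89 at -0.57 ± 0.05 (SE) and SPL2, which was not well above background in RM11-1a and YLK806, and adjusted over the list alone 11 fell and 1 rose. The opposite exchange did not move PHO89 the opposite way, since it was at -1.44 in YLK804 and -0.31 in YLK806, so its average rests on YLK804. The lists of the mitochondrial ribosome, mitochondrial translation factors and ribosome biogenesis tested downward with medians of -0.10, -0.09 and -0.07, and no member of the 3 passed by limma, while over all genes 639 had an unadjusted p under 0.05. Without RM11-1a replicate 9 or 11 there were 13 and 11 lists that passed. The adjusted p was 0.516 for phosphate and 0.982 for the other 3 with an estimated correlation.

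The expression difference between the backgrounds was present in the SAL1 strains. Across 5831 genes YLK804 minus YLK806 correlated with BY4716 minus RM11-1a with Pearson's r = 0.883 and Spearman's rho = 0.888, with no array shared. Without the mating type, marker and pyrimidine genes r was 0.938. Genes are not independent replicates, so no p is given.

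**Figure D3:**
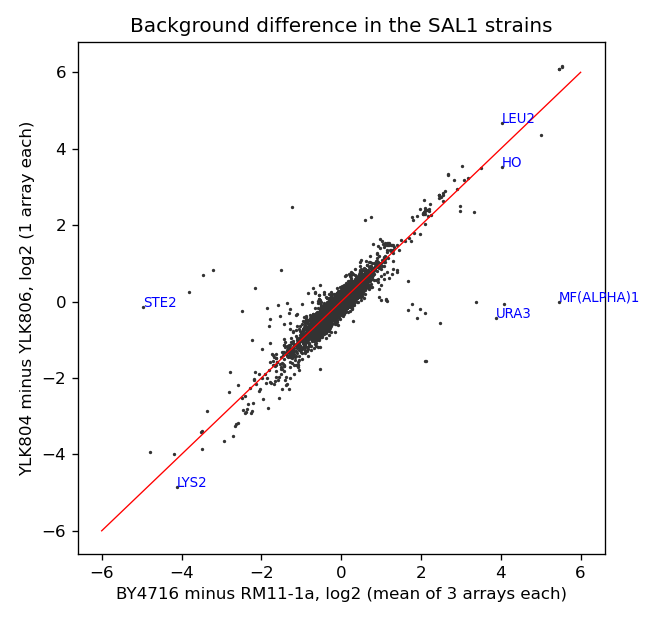
Difference of YLK804 and YLK806 (vertical axis, log2) against the difference of BY4716 and RM11-1a (horizontal axis, log2), 1 point per gene, with a line at equality and 6 genes named. Most genes follow the line with r = 0.883, and STE2, URA3 and MF(ALPHA)1 lie near 0 on the vertical axis.

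The shift of each exchange strain toward the donor of its allele was measured across genes. For YAD350, its difference from BY4716 was set against the difference of RM11-1a from BY4716. The covariance was 0.0603, against 0.00193 in simulated unchanged arrays that share the BY4716 arrays, and r was 0.299. The simulated r of 0.347 cannot be compared with it, since the simulated parental arrays held no difference between the strains. Of the genes higher in YAD350, 798 were also higher in RM11-1a, where independent lists share 515, and of the lower ones 671 were lower in both, where independent lists share 360. Part of the excess may come from the shared BY4716 arrays. In YLK804 the covariance was 0.0369, and r fell from 0.221 to 0.030 without the mating type, marker and pyrimidine genes. In YLK806, with BY4716 as the donor, the covariance was -0.00349 and r was -0.025.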

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

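All tests in this part were chosen after the results were seen, except the other splits of the parental arrays and the correlation of YAD350 minus YLK804 with the parental difference.

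The difference made by the SAL1 allele, RM11-1a minus BY, was tested between the 2 backgrounds and differed for 2270 genes. This test equals the sum of the shifts of YLK804 and YLK806 from their parents, so anything common to both later arrays enters it in full. Among the genes named for the contrast, the difference between backgrounds was 4.66 for STE2, 3.86 for BAR1, 3.35 for MFA1, 2.39 for MFA2, 1.94 for URA1, -2.34 for AFB1, -2.83 for MF(ALPHA)2, -0.47 for SAL1 and -0.25 for SUL1 on the log2 scale. The value of MF(ALPHA)2 is not a measured size, since it was not well above background in RM11-1a, YLK804 and YLK806.

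The 3 later arrays shared a shift from their parents, with 2925 genes called for their mean shift and 290 genes higher and 168 lower in all 3. A changed reference channel is a candidate explanation: the Cy3 channel carried a share of 0.738 of the shift, and between 0.615 and 0.883 with any 1 of the 3 arrays left out, against -0.037 for the parental difference. The exchanged SAL1 alleles would move YLK804 and YLK806 in opposite directions, and their shifts correlated with r = 0.680 without the mating type, marker and pyrimidine genes and 0.528 over all genes, which argues against them. The newer extraction software was not used for YAD350. The YAD350 shift correlated with that of YLK806 with r = 0.413 without those genes and 0.402 over all genes. No array was shared, so this argues against the software as the whole cause. The Cy3 share was 0.781 in YLK804 and 0.749 in YLK806, against 0.355 in YAD350. YLK804 and YLK806 also shared a scan day, so a part from the software stays open. The part in the Cy5 channel stays open, since the later scan days held none of the parental arrays.

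The mitochondrial ribosome genes were higher in YAD350, where their Cy3 channel was higher by a median of 0.094 and a reference effect needs a fall. The median of the list was -0.12 in YLK804, which argues against a shift common to the later arrays as the whole cause, and with the mean shift of YLK804 and YLK806 subtracted 37 genes rose in YAD350, 34 of them among the 42 called before. In YLK806 the list rose with a median of 0.09, so a smaller part shared with that array stays open. YAD350 minus YLK804 correlated with RM11-1a minus BY4716 with r = 0.348 across genes outside the mating type, marker and pyrimidine genes. No array was shared. A move toward RM11-1a, the strain known to carry the residue that the MKT1 replacement brings in, would give such an r. It is not specific to this list, and phosphate genes went the other way, with medians of -0.90 in RM11-1a and 0.76 in YAD350. LEU2 was also low in RM11-1a and YAD350 but not in YLK804. The added histidine, the other markers of BY4742, the growth of a single culture and its own scan day were not tested and stay open beside the MKT1 allele.

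The calls in the SAL1 contrast held 23 mating type, marker and pyrimidine genes, where 0.284 are expected from their 34 among the genes tested. YLK804 and BY4716 differ in mating type and URA3 by genotype, so such an excess was fixed in advance and does not test a source. LEU2, among the 23, was at -0.10 in YLK804 and -0.74 in YLK806, and it was not well above background in RM11-1a and YLK806. Outside the listed genes, 7 of 26 calls were made in both backgrounds with opposite signs, among them COS8, GSC2, SNZ2, SUL1, YIR043C and YPL088W. That number is too small to settle whether an allele effect present in both backgrounds accounts for the 26, and the SAL1 allele stays open for these 7. The 26 held AFB1, a known gene of MATalpha cells, and TIM9 beside URA3, so background genes remain among them.

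For the parental count of 3697 genes, 1 of the 10 splits of the 6 arrays gave as many, the real one, and the highest of the other splits gave 0. With 10 splits the share cannot fall under 0.05.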

How the results depend on the processing

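The alternatives with the mating type, marker and pyrimidine genes left out, scan day as a random block, the mean shift of YLK804 and YLK806 subtracted, or YLK804 as the comparison array were chosen after seeing the data. Under the alternatives tried, the parental count stayed within 1.5 times of 3697. Of 2241 alternative values for named genes, 2119 kept their direction and side of the threshold, 86 no longer passed, 12 newly passed and 24 reversed. In the Agilent ratios 41 of 204 called named values grew and 3 shrank by over 1.5 times, among them HO in RM11-1a at -7.03. LEU2 in RM11-1a also grew, but no value is given, since it was not well above background there. Unless named below as following from fewer arrays or genes, the cause was not tested. Dim genes limit folds to bounds, since backgrounds lay between 21 and 32.

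For YAD350, 1805 genes were called with the mean shift subtracted and 1361 against YLK804, a test of 1 array against 1 array that differ in mating type and scan day, so it does not isolate the MKT1 allele. Median centring gave 629 genes for YLK804 and 800 for YLK806. With the ratios of the exchange strains turned, 4427, 4039 and 3649 genes were called for YLK804, YLK806 and the SAL1 contrast. That contrast gave 81 with scaling between arrays, 32 with the stricter filter, which tests fewer genes, 156 with scan day as a fixed block, which leaves 1 residual degree of freedom, and 26 without the mating type, marker and pyrimidine genes. Leaving out 1 parental array, so that fewer arrays set the spread, gave 592 to 1448 genes for YLK804, 856 to 1562 for YLK806 and 28 to 64 for the SAL1 contrast.

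With an estimated correlation 0 lists passed in each of the 5 comparisons, by camera, and the mating type lists also failed. With the shift subtracted 16 lists passed for YAD350, with the respiratory chain lost and translation factors rising in 13 cases, and the mating type lists passed since YLK804 is MATa. Of the 16, 0 passed with an estimated correlation. Then the deposited Agilent ratios gave 4 for YLK806, and leaving out 1 array gave 6 to 13 for the SAL1 contrast. The r of the shift toward the donor was 0.243 for YAD350, 0.266 for YLK804 and 0.011 for YLK806 in the Agilent ratios, and 0.030 for YLK804 without the mating type, marker and pyrimidine genes.

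The replicate number as a replicate block gave 3396 genes between the parental strains, and as a random block 2761 for YAD350, 1244 for YLK804, 1323 for YLK806 and 47 for the SAL1 contrast. Deviations of arrays with the same number correlated with r = -0.208 for 7, 0.136 for 9 and -0.175 for 11, and only number 9 had its own number as best partner. The arrays numbered 9 also shared a scan day, so the numbers were not taken to pair the arrays. A fixed scan day block could not be estimated for the 3 strains with 1 array. The highest probe per gene was not run, since each gene had 1 probe.

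The named genes that reversed had not passed, except STE3 in YLK806. In the deposited Agilent ratios STE3 was at 0.20 and HO at -0.63 in YLK806, HO at 0.22 in the SAL1 contrast, MFA1 at 0.22, SAL1 at -0.023 and MKT1 at -0.024 in YAD350, and SWS2 at -0.0035 in YLK804. HO was not well above background in YLK806, so its values here are not measured sizes. With median centring MFA1 was at 0.030, SAL1 at -0.00205 and MKT1 at -0.056 in YAD350, SWS2 at -0.081 in YLK804, and STE6 at -0.023, SWS2 at -0.041 and END3 at -0.048 in YLK806. LYS2 in YAD350 was at 0.0068 with no background correction. Leaving out 1 parental array gave -0.058 to 0.069 for END3 in RM11-1a, -0.083 to 0.058 for LYS2, -0.049 to 0.073 for BAR1 and -0.0073 to 0.025 for SAL1 in YAD350, -0.034 to 0.010 for AGA2 and -0.039 to 0.088 for END3 in YLK806, and -0.032 to 0.022 for PMS1 in the SAL1 contrast.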

Other observations

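The genes of these paragraphs other than URA1, LEU1 and MFA1 were chosen after their values were seen. In the strains labelled as lacking URA3, the pyrimidine gene URA4 was higher by 1.35 in RM11-1a, 1.04 in YAD350 and 1.16 in YLK804, and URA1 by 2.16 ± 0.05 in RM11-1a, 2.19 ± 0.07 in YAD350 and 2.23 ± 0.07 in YLK804 (SE), each against BY4716. In RM11-1a and YAD350, where LEU2 was not well above background, the leucine synthesis gene LEU1 was higher by 2.36 in RM11-1a and 2.17 in YAD350, and the aminotransferase gene BAT1 by 2.03 and 1.60. In YLK804, where LEU2 was at 1.14, LEU1 was at 0.10 and BAT1 at -0.03. The lists of pyrimidine and branched-chain genes passed in none of the 5 comparisons.

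The gene TIM9, next to URA3 on the chromosome, was at -0.82 in YAD350, -1.25 in YLK804 and 0.54 in RM11-1a. Beside HIS3, DED1 was at 0.48 in YAD350, 0.47 in YLK804 and 0.44 in YLK806, while HIS3 was low in YAD350 alone. MFA1 was at 3.12 in YLK804 and 0.83 ± 0.04 (SD, n = 3) in RM11-1a, both of mating type a.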
